A study of Mus musculus with 5 samples.

How the data were processed

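The series profiled mouse pancreatic cells sorted on the Dclk1-ZSGreen reporter, with or without TdTomato, in 5 droplet libraries (10x Genomics per the labels), 1 per group. The deposited values are whole-number UMI counts per gene and cell barcode, without normalization. Per the submitters' processing notes, Cell Ranger was run on mm10; its version, the filters on genes and cells and the pooling of libraries are not given in the sources used here. Every gene in the table was counted in 5 or more barcodes. The table joins all libraries under 1 barcode suffix and gives no library names, so the sample analysed is the pool of all libraries.

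Barcodes fall into 5 alphabetically sorted stretches (runs), in each of which the order starts anew; 6 barcodes occur in more than 1 run. Runs served only as unlabelled technical batches for doublet calling and for comparisons within 1 run, and no run was matched to a group. Barcodes with fewer than 200 detected genes (78) or more than 20% mitochondrial counts (149, over 13 mitochondrial genes) were removed, 215 in all. Scrublet, run per run in scanpy, called 115 of the remaining 6452 barcodes doublets (1.78%), of which 99 were in run 1, and 6337 cells were analysed. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered over 15 neighbours by the Leiden method at resolution 1, with a fixed seed. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

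Marker lists for 25 cell types, 23 program gene lists, the comparisons, the alternatives and the rule for named genes were written before the data were examined. Of 281 marker genes 172 were measured, and of 295 program genes 235. A cluster took the name of a type, with "-like" added, when at least 3 of its markers were among the 50 genes of highest fold (CPM plus a pseudocount of 1, against all other cells; CPM of at least 50, in at least 10% of the cells, and at least 2-fold). A cluster stayed unnamed where another type also had 3 markers there, where another type had more markers among the first 10 genes, or where its median UMI count was low (under the pool's median divided by 3) with none of its type's markers among the first 10. Other clusters are called by their leading gene. The rule names the markers that define a cluster, the 10 genes of highest fold of each tuft-like or unnamed cluster, and always Dclk1, Kras, Bhlha15, Spib, Pou2f3, the reporter transcripts and Hbegf. Symbols were matched to the reference annotation, which held 12895 of the 12900.

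With 1 library per group and no map of cells to libraries, no test across samples was possible, and cells were not treated as replicates. Levels are CPM of the summed counts of a class with exact Poisson 95% intervals; ratios have exact conditional binomial 95% intervals; shares have exact Clopper-Pearson 95% intervals. All of these cover counting error only. The limit that a count of 0 allows was taken as 3 counts. Shares of cells with a gene were taken after thinning each cell to 1000 UMIs at random, with unthinned shares beside them. In place of the library comparisons, 3 pairs of cell sets within 1 run were compared. These were chosen after the clusters were seen: Tuft-like against other epithelial clusters (Epcam of at least 500 CPM), Cldn4-led against Acinar-like, and Timp1-led against Fibroblast-like cells. Each list is described by the median log2 ratio of CPM + 1 over members with a count and, with 3 or more members, by its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. From each list up to 4 members of highest mean CPM were considered for naming, and in each direction up to 10 genes of highest ratio among those with at least 100 CPM in the higher set and an interval wholly beyond 2-fold.

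The code was tested on simulated data made from each pair of sets with 200 changed genes. For changes of 1.5-fold, 2-fold and 4-fold, intervals held the true ratio for 92.5 to 98.5% of genes, and the direction was right for 94.0 to 100.0%. Of 200 lists without a change, 4.5, 2.5 and 4.0% fell in the outer 5% in the 3 pairs. Both simulated sets were drawn as Poisson counts from a common profile, the model behind the intervals, so the simulation checks the code only. It leaves out the clumping of UMIs in a few cells and the difference in enzyme share between real sets. Alternatives covered clustering settings, filters, doublets, thinning, scaling, the pseudocount and a count minimum. Depth over the pool was 66228405 UMIs.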

Results

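Single cells were sorted on the ZSGreen reporter of Dclk1, a microtubule-associated kinase used as a tuft cell marker, from mouse pancreas and profiled in 5 droplet libraries. The labels give 5 groups of 1 library each: ZSGreen+ cells of normal pancreas, and ZSGreen+ and ZSGreen+/TdTomato+ cells at 2 and 16 weeks after KRAS activation. The KRAS mice carry a Mist1-Kras-TdTomato construct by name, after Mist1 (Bhlha15), an acinar transcription factor. The table analysed pools the libraries and gives 66228405 UMIs (unique molecular identifiers, 1 per counted transcript) over 12900 genes and 6667 barcodes. UMIs per barcode ran from 101 to 94658, with a median of 5760.0, and the median number of detected genes was 1699. No barcode carries a library name, so the comparisons between the 5 libraries were not run, and the data were described as 1 pooled sample without replicates.

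The barcodes stand in 5 alphabetically sorted runs, called run 1 to run 5 here and assigned to no group. Run 1 held 2741 barcodes and 16735753 UMIs, run 2 held 495 and 2244862, run 3 held 1866 and 30725989, run 4 held 1199 and 12354150, and run 5 held 366 and 4167651. Median UMIs per barcode were 4979 in run 1, 3273 in run 2, 8993.5 in run 3, 6227 in run 4 and 7519.5 in run 5. Acinar digestive enzymes took 1.30% of the UMIs of run 1, 0.019% of run 2, 54.9% of run 3, 10.2% of run 4 and 3.70% of run 5. Of the barcodes, 6337 passed the filters and the doublet call.

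The 6337 cells formed 24 clusters, and fixed marker lists named 12 of them, in 10 classes. The Tuft-like class held 991 cells, 15.6% of the pool (exact 95% interval 14.8 to 16.6%), and 15 Tuft markers were among its 50 genes of highest fold: Dclk1, Pou2f3, Trpm5, Avil, Gfi1b, Sh2d6, Hck, Rgs13, Ltc4s, Gng13, Il17rb, Siglecf, Matk, Hmx2 and Nrgn. Its 10 leading genes were Gng13, Nrgn, Rgs13, Cdhr2, Sh2d6, Strip2, Spib, Adh1, Siglecf and Hmx2, with Gng13, a taste G protein subunit, at 284-fold of the other cells. Acinar-like cells numbered 975, Gastric-metaplasia-like cells 578, Macrophage-like cells 413, Endothelial-like cells 402, Ductal-like cells 360, Fibroblast-like cells 228, Dendritic-like cells 172, Schwann-like cells 42 and Pericyte-like cells 18. Of the Tuft-like cells, 978 came from run 1, as did 568 Gastric-metaplasia-like cells, while 859 Acinar-like cells came from run 3 and 387 Endothelial-like cells from run 4. A class drawn almost wholly from 1 run cannot be separated from the library behind that run. Tuft-like cells also had the highest median mitochondrial share of any class or cluster, 9.53%, against 3.98% in Gastric-metaplasia-like cells.

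Another 12 clusters did not meet the full naming rule and are called by their leading gene. That gene need not be in most cells of its cluster: the share of cells with it ran from 16.3% for Arg1 and 18.8% for Lypd8 to 100% for Spink4. The Arg1-led cluster (668 cells) was led by Arg1, Ccl6, Adap2os, A930007I19Rik, Mmp12, Ccl9, Clec4d, Osm, Fcgr4 and Ccl4, several of them myeloid chemokines and receptors. The Gsta1-led cluster (448 cells) was led by Gsta1, Duoxa2, Mcpt2, Krt20, Duox2, Phgr1, Gsto1, Cyp2c65, Oit1 and Rbp2, among them the keratin of differentiated gut epithelium, Krt20, and the oxidase pair Duox2 and Duoxa2. Genes of the Gastric metaplasia program list took 2.78% of its UMIs, near the 2.90% in Gastric-metaplasia-like cells. The Timp1-led cluster (289 cells) was led by Timp1, Tnc, Saa3, Thbs4, Col8a1, Cthrc1, Lox, Ltbp2, Fbn2 and Tagln, most of which encode matrix proteins or matrix-modifying enzymes. It held 4 Fibroblast markers, Col1a1, Col1a2, Col3a1 and Mfap5, among its 50 genes of highest fold, and stayed unnamed because a Pericyte marker, Tagln, and no Fibroblast marker was among its first 10. The Cldn4-led cluster (164 cells) was led by the tight-junction genes Cldn4 and Cldn6 and by Mia, Shisa4, Gc, Ptf1a, Fetub, Rgs5, Reg3g and Ctsl. The Pla2g2d-led cluster (142 cells) was led by Pla2g2d, Lyz1, Cst7, Art2b, Spic, Ly6i, Tgm1, Il18bp, Cd4 and Sell. The Rbpjl-led cluster (129 cells) was led by the acinar transcription factor Rbpjl and by Col7a1, Arhgef26, Lars2, Nphs1, Sugp1, Tmem191c, Gm15915, Ankrd24 and Slc1a3, at the lowest median depth of all clusters, 1742 UMIs.

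The smaller unnamed clusters included lymphoid, dividing, hormone and mucus genes among their leading genes. The Cxcl13-led cluster (69 cells) was led by Cxcl13, Madcam1, Cd79a, Ptprcap, Ubd, Cd3d, Ager, Mfge8, Cd3g and Pthlh, and held 7 T cell and 3 B cell markers among its 50 genes of highest fold, so that no single type named it. Mitotic genes led the Top2a-led cluster (62 cells), with Top2a, Hist1h1b, Nusap1, Mki67, Hist1h2ae, Birc5, Kif15, Aurkb, Ckap2l and Kif11. The Cd209f-led cluster (60 cells) was led by Cd209f, Cd209g, Lyve1, Ccl8, Cd163, F13a1, Ccl24, Hal, Folr2 and Vsig4, which include scavenger receptors of tissue macrophages. Insulin and secretory granule genes led the Ins2-led cluster (60 cells), with Ins2, Scg2, Pcsk2, Pcsk1n, Ppp1r1a, Scg5, Nnat, Syt13, Cox6a2 and Prlr. The Spink4-led cluster (35 cells) was led by Spink4, Tff3, Fcgbp, Gm15848, Wfdc18, Ly6d, C4bp, Lgals2, Ugt2b35 and Sptssb, of which Tff3 and Fcgbp are goblet cell products. The Lypd8-led cluster (32 cells) was led by Lypd8, Cdc20, Sapcd2, Ccna2, Ube2c, Cdca3, Ect2, Plk1, Cenpf and Hist1h2ap, mostly cell cycle genes. Genes of the Gastric metaplasia program list took 2.18% of its UMIs.

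The identity of Dclk1 cells was the question that the series states. Dclk1 (ENSMUSG00000027797.15, GRCm38 chromosome 3, 55242364 to 55539068, plus strand) was counted in 1757 of the 6337 cells, 27.7%, and in 1100 of 6310 cells, 17.4% (16.5 to 18.4%), after each cell was thinned to 1000 UMIs; 27 cells below that depth were left out. Tuft-like cells held 88.8% of all Dclk1 UMIs and 83.0% (80.6 to 85.2%) of the cells with Dclk1 after thinning, and 56.1% (53.8 to 58.5%) of those without thinning. This rests on run 1, where 902 of the 979 thinned cells with Dclk1 were Tuft-like, 92.1% (90.3 to 93.7%); in runs 2 to 5 it was 11 of 121, 9.09% (4.63 to 15.7%). In that class 92.2% (90.4 to 93.8%) of cells had Dclk1 after thinning and 99.5% before it, at 3014 CPM (counts scaled to the total counts of the class) and a median depth of 4475 UMIs. As the background type, Macrophage-like cells had Dclk1 in 0 of 412 thinned cells, which allows a share of up to 0.728%, and in 0.242% of cells unthinned, at a median of 9456 UMIs; only 2 of the 413 lay in run 1, so this is the background of runs 3 and 4. In run 1 the Arg1-led cells, with Dclk1 in 3.87% of thinned cells, are the nearest to a background.

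Stromal cells and some epithelial clusters carried Dclk1 at lower levels. Timp1-led cells had it in 16.3% (12.2 to 21.1%) of thinned cells and 51.9% of unthinned cells, at 179 CPM and a median of 6638 UMIs. Fibroblast-like cells had it in 13.6% (9.43 to 18.7%) of thinned and 58.3% of unthinned cells, at 139 CPM and a median of 8009 UMIs. Both classes showed this in more than 1 run: 17.3, 9.09 and 23.1% of thinned Timp1-led cells in runs 1, 2 and 3, and 12.4 and 19.0% of thinned Fibroblast-like cells in runs 3 and 4. Cldn4-led cells of run 3 had it in 10.1% (5.66 to 16.4%) of thinned cells and 53.2% unthinned, at a median of 13074 UMIs. In Acinar-like cells of the same run it was 0 of 858 thinned cells, which allows up to 0.35%, and 3 of 859 unthinned. Enzymes took 74.2% of the UMIs of these Acinar-like cells and 30.9% of those of the Cldn4-led cells. Thinning thus leaves fewer other UMIs in Acinar-like cells, and the 2 thinned shares are not at equal depth for Dclk1. The other runs held few Cldn4-led cells, with Dclk1 in 1 of 9 thinned cells in run 1 and in 0 of 13 in run 4, which allows up to 23.1%. Acinar-like cells of run 1 had it in 4 of 28 thinned cells, 14.3% (4.03 to 32.7%), and those of runs 4 and 5 in 0 of 67 and 0 of 20, which allows up to 4.48% and 15%. Cxcl13-led cells of run 5 had Dclk1 in 9 of 36 thinned cells, 25% (12.1 to 42.2%), and in 0 of 25 in run 4, which allows up to 12%. Lypd8-led cells of run 1, an epithelial cluster, had it in 4 of 25 thinned cells, 16.0% (4.54 to 36.1%), and in 40.0% unthinned. Their level was 124 CPM (91.2 to 165), and whether it came from tuft-like cells was not tested. Gastric-metaplasia-like and Gsta1-led cells of run 1 had it in 4.41% and 3.14% of thinned cells, near the 3.87% of Arg1-led cells of that run. Unthinned shares, in the same order, were 23.2%, 18.8% and 7.99%, at medians of 6977, 7066 and 2477 UMIs. Levels were 70.6 CPM (63.1 to 78.9) in Gastric-metaplasia-like, 29.5 (24.0 to 36.0) in Gsta1-led and 31.7 (21.05 to 45.8) in Arg1-led cells. The level of Gastric-metaplasia-like cells thus lay above that of Arg1-led cells, and their share was not read as background. The level of Gsta1-led cells lay within the interval of Arg1-led cells, so it was not told apart from background. Thinned Ductal-like cells had Dclk1 in 4.46% (2.57 to 7.14%) over the pool and in 10 of 229 in run 4, 4.37% (2.11 to 7.88%). In that run it was 0 of 192 Macrophage-like and 0.525% (0.064 to 1.88%) of Endothelial-like cells. Among thinned Ductal-like cells it was 3 of 19 in run 1, 1 of 18 in run 3 and 2 of 84 in run 5. The 19 cells of run 1 held 56 of the class's 174 Dclk1 UMIs, at 501 CPM (378 to 650). Levels were 183 CPM (128 to 254) in Acinar-like cells of run 1 and 359 CPM (296 to 431) in Cxcl13-led cells of run 5. Whether the Dclk1 UMIs of these 3 sets came from tuft-like cells was not tested. Dclk1 was found in 0.505% of thinned Endothelial-like cells and in 0 of 172 thinned Dendritic-like cells, which allows up to 1.74%.

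**Figure D1:**
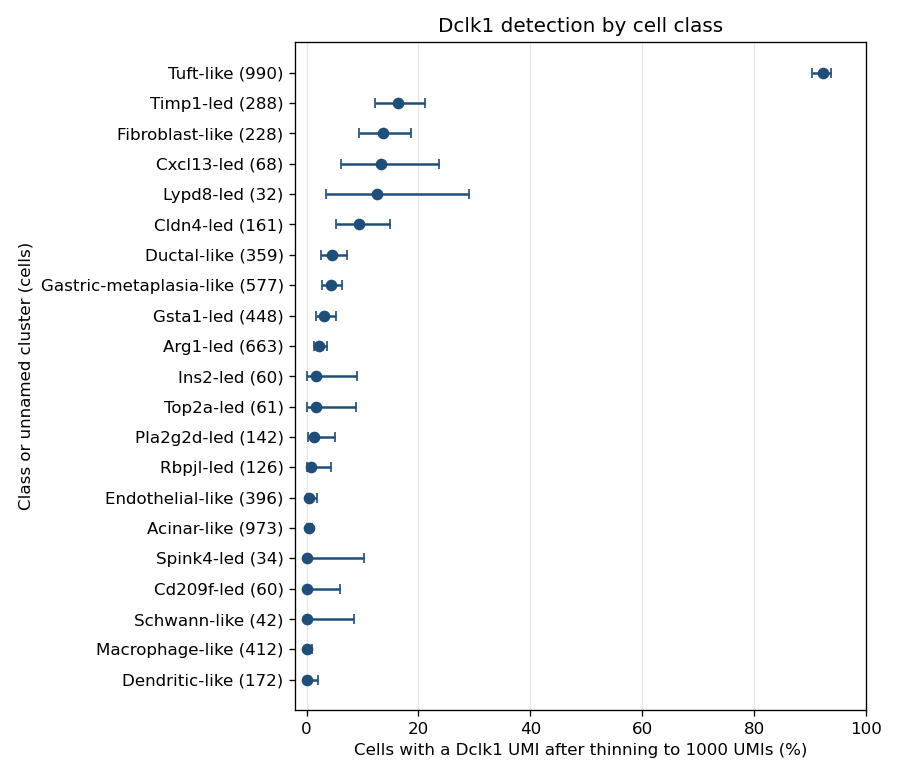
Percent of cells with a Dclk1 UMI after thinning to 1000 UMIs (x axis), by class or unnamed cluster (y axis, thinned cells in brackets, at least 30 cells); points are shares of the pool and bars exact 95% intervals. Tuft-like cells stand at 92.2% and Timp1-led cells at 16.3%, with 0 of 412 Macrophage-like cells.

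The tuft cell transcription factors Spib and Pou2f3 were concentrated in the Tuft-like class. Spib reached 976 CPM (949 to 1003) there and was counted in 63.9% of thinned cells, and the next highest level was 153 CPM (119 to 193) in the Cxcl13-led cluster, whose leading genes include lymphocyte genes. Pou2f3 reached 190 CPM (179 to 203) in Tuft-like cells and was at 4.06 CPM in Gastric-metaplasia-like cells; no UMI was counted in Macrophage-like cells. Hbegf, the mouse gene of the growth factor whose human form is the diphtheria toxin receptor (DTR), stood at 747 CPM in Tuft-like, 546 in Spink4-led, 295 in Ductal-like and 259 in Gastric-metaplasia-like cells. Whether reads of the DTR transgene were counted under Hbegf is not given in the sources used here, so each Hbegf value holds for the gene together with any such reads. Kras stood at 38.7 CPM in Tuft-like, 4.51 in Acinar-like, 107 in Cldn4-led and 136 in Endothelial-like cells, in counts that do not separate the mutant from the wild-type allele. Enzymes took 74.0% of the UMIs of Acinar-like and 32.3% of those of Cldn4-led cells, which lowers the CPM of every other gene there, so these Kras levels are not on an equal footing. Bhlha15 and the reporter transcripts were not analysed here.

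Tuft-like cells (978) were set against the other epithelial cells of run 1 (1084, mostly Gastric-metaplasia-like and Gsta1-led), a comparison chosen after the clusters were seen. Genes of tuft cell signalling were higher in Tuft-like cells: of the Taste transduction list 4 of 5 members were higher, with Gng13 at 63.4-fold (57.2 to 70.5) and the cation channel gene Trpm5 at 62.9-fold (54.1 to 73.6). Of the Eicosanoid synthesis list 6 of 10 members were higher, including the leukotriene genes Alox5ap (65.0-fold) and Ltc4s (51.1-fold) and the prostaglandin genes Hpgds (54.7-fold) and Ptgs1 (50.5-fold). Among the Tuft transcription factors 9 of 10 were higher, with Hmx2 at 79.7-fold, Spib at 68.8-fold (57.5 to 83.1), Pou2f3 at 53.8-fold (37.4 to 80.2) and Sox9 at 2.31-fold. Dclk1 was 48.1-fold higher (44.1 to 52.5) and Hbegf 3.48-fold higher, while Kras was 2.07-fold lower (1.76 to 2.44). The apical cytoskeleton list (9 of 13 higher) had Cdhr2 at 68.8-fold, Espn at 47.5-fold and Avil at 18.0-fold, and the hypoxia and glycolysis list (9 of 11 higher) had Ldha at 2.27-fold and Aldoa at 1.61-fold, with Hk2 84.3-fold lower. Other genes with high ratios were the hormone gene Sct (107-fold), Nrgn (91.1-fold), Siglecf (75.2-fold) and Hck (70.0-fold).

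The other epithelial cells of run 1 were higher in genes of the Gastric metaplasia and the Reg and acute phase lists. All 5 measured Gastric metaplasia genes were lower in Tuft-like cells, with a median log2 ratio of -5.63, and Tff2 was 56.4-fold and Ctse 58.6-fold higher in the other cells. All 12 Reg and acute phase genes were lower in Tuft-like cells, with a median of -2.18, and of -4.24 without the 1% of cells with the most enzyme UMIs in each set. All 15 Proliferation genes were lower with a median of -2.03, but 25 Lypd8-led cells held 54.2% of the list's UMIs in the other set; without them 13 of 15 were lower, with a median of -0.72. The RAS-MAPK response list was lower for 13 of 14 members (median -1.59), Hbegf, with any DTR reads, being the exception, and the Immediate-early stress list for 13 of 15 (median -1.49). Of 14 Duct and metaplasia genes 11 were lower (median -1.74), whereas Krt8 was 2.62-fold and Krt18 3.30-fold higher in Tuft-like cells. The Secretion and mucus list was lower for 9 of 11 members (median -1.32) and the Acinar enzymes for 18 of 21 (median -1.49). A few cells held most of their set's enzyme UMIs on both sides, 79.8% in 9 of the 978 Tuft-like cells and 76.2% in 10 of the 1084 other cells; without these the enzyme median was -1.48, again with 18 of 21 lower. The genes most in favour of the other cells also included Gsta1 (140-fold), the cyclin gene Ccnd2 (106-fold), Mal (91.8-fold), Sprr2a3 (80.8-fold), Duox2 (78.0-fold), S100a6 (68.8-fold) and Mcpt2 (67.3-fold).

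Median log2 ratios of the higher lists in that comparison were 3.72 for Taste transduction, 2.57 for Eicosanoid synthesis, 2.40 for Tuft transcription factors, 1.72 for the apical cytoskeleton and 1.18 for hypoxia and glycolysis. These 13 lists lay in the outer 5% of 10000 random lists matched on expression, a description of 2 cell sets and not a test between animals. Lists inside that range were the Tuft-ILC2 circuit (median 0.48, though Il17rb, the IL-25 receptor subunit, was 57.1-fold and Il13ra1 7.60-fold higher), Progenitor and stem (0.53, with Cd24a 5.72-fold higher), MHC class I (0.24), Interferon response (0.11), Unfolded protein response (0.01), Neuroendocrine (0.13), EMT and mesenchyme (-0.21) and Acinar transcription factors (-0.68). MHC class II had 2 and Islet hormones 1 measured member and were not ranked. The median gene shifted by 0.10 log2. A clustering without Dclk1, Spib, Kras and the list genes that are no markers gave 978 of the 978 and 1083 of the 1084 cells again. List genes that are also markers, such as Trpm5, Gng13, Pou2f3 and Alox5ap, stayed in that clustering. It therefore could not separate the places of the lists from the way the sets were made. Intervals cover counting error only, and the sets were drawn from the same counts that they are compared on.

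Cldn4-led cells of run 3 (139) were set against the Acinar-like cells of that run (859), also a choice made after the clusters were seen. Enzymes took 30.9% of the UMIs of the Cldn4-led cells and 74.2% of those of the Acinar-like cells, and the median gene was 1.73 log2 higher in CPM and 0.88 with enzymes left out of the total; ratios without enzymes follow. Duct and metaplasia genes were higher for 13 of 14 members, with a median of 3.34, and RAS-MAPK response genes for 14 of 14, with a median of 2.68. The sets were made by clustering on these counts, and 8 of the 14 Duct and metaplasia genes, Cldn4 among them, were variable genes used there. Where the lists fall is thus not independent of how the sets were made. Dclk1 was 166-fold higher, from 263 UMIs against 4, Kras was 9.66-fold and Hbegf 54.5-fold higher, and no Spib UMI was counted in the Cldn4-led cells. The apical cytoskeleton list had a median of 3.14, Tuft transcription factors 2.85, MHC class I 2.67, Eicosanoid synthesis 1.96 and Proliferation 1.68. In the Tuft transcription factors the highest counts were for Sox4 and Sox9, which act outside tuft cells too, and Hmx2 was counted 32 times against 0. Pou2f3 was counted only 2 times against 1, with a CPM ratio interval of 0.704 to 798.

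In total CPM the genes most in favour of the Cldn4-led cells were Ctla2a, S100a10, Cldn4, S100a6, S100a11, Anxa2, Spp1, Ly6a, Basp1 and Krt7. Cldn4 was counted 1569 times against 6, Krt7 was 428-fold higher (279 to 694), Anxa2 463-fold (325 to 683) and Spp1 345-fold (275 to 439); Ctla2a UMIs came from 13 of the 139 cells. Every measured Acinar enzyme was lower (21 of 21, median -3.68 without enzymes in the total, -2.25 with them), which follows in part from the markers that named the Acinar-like class. Beside enzymes such as Cela1 (15.6-fold lower), Cela3b, Pnlip, Try4, Ctrl and Cel, the genes Gal (21.6-fold lower), Pla2g1b (17.0-fold lower), Zg16 and Reg3d were lower. Of the acinar transcription factors, Ptf1a was 1.69-fold higher without enzymes in the total, a log2 ratio of 0.75 that lies under the median gene's 0.88, and Rbpjl was 3.03-fold lower. The Unfolded protein response lay below the median gene, at 1.25 against 1.73 in CPM and -0.16 against 0.88 without enzymes. Reg and acute phase genes also lay below it, at 0.57 in CPM and 0.09 without enzymes, where the list was at percentile 13.3 of the random lists, inside the range. With the mean over cells of each cell's counts, the Proliferation list fell at percentile 71.5, MHC class I at 78.0 and Tuft transcription factors at 92.9 of the random lists, inside the range, which 10 lists had left in CPM. Proliferation was also inside it with size factors (percentile 96.8) and with a pseudocount of 10 (90.1), as was MHC class I with that pseudocount (96.9). Single cells held 9 of 16 Mki67, 10 of 14 Top2a and 11 of 18 Birc5 UMIs of the Cldn4-led set. Without the 5% of cells with the most Proliferation UMIs in each set, which held 44.8% of the list's UMIs in Cldn4-led and 65.1% in Acinar-like cells, the CPM median fell from 2.23 to 1.55, under that of all genes, 1.72, though the list stayed in the outer 5% of the matched lists.

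Timp1-led cells of run 3 (108) were set against the Fibroblast-like cells of that run (161), and both sets carry Fibroblast markers. This was the last comparison chosen after the clusters were seen. The sets were made by clustering on the same counts, and 8 of the 15 Proliferation genes were variable genes used there. Where the lists fall is thus not independent of how the sets were made. All 15 Proliferation genes were higher in Timp1-led cells, with a median log2 ratio of 2.43, and of 2.48 without the 5% of cells with the most UMIs of the list in each set. The cells left out held 63.4% of the list's UMIs in Timp1-led and 27.6% in Fibroblast-like cells. Mki67 UMIs came from 15 of the 108 Timp1-led cells, more than the 5 left out. The second median therefore cannot tell a dividing subset from a rise in the whole set. Tyms was 5.56-fold (3.72 to 8.37) and Hmgb2 5.48-fold (4.16 to 7.31) higher. Dclk1 was higher by 1.65-fold (1.35 to 2.01), Hbegf by 6.10-fold, and Kras by 1.10-fold with an interval from 0.789 to 1.52. Tagln, a contractile gene, was 53.8-fold higher (41.1 to 72.1), and Nes was counted 206 times against 1, a ratio interval of 36.6 to 8181. Spp1 was counted 1554 times against 1, in 31 of the 108 cells, and Prc1 140 times against 0. Igkc, Jchain and Slpi also stood high, but 18118 of 18120 Igkc UMIs, all 2570 Jchain UMIs and all 224 Slpi UMIs came from 1 cell each.

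Fibroblast-like cells were higher in Sema3c (267 UMIs against 2, a ratio interval of 36.6 to 1107), Emilin2 (25.5-fold), Efemp1 (22.8-fold), Ackr3 (20.9-fold), Ces1d (15.7-fold), Clec3b (14.9-fold), Pcsk6 (14.8-fold), Ly6c1 (14.1-fold), Cd55 (244 against 20.4 CPM) and Gstm1 (11.2-fold). Of the Duct and metaplasia list 8 of 11 members were higher in Timp1-led cells (median 1.36), led by Spp1, and the list fell to percentile 90.2, inside the range, with members of at least 20 counts. Immediate-early stress genes were lower for 13 of 15 members (median -0.62), but this turned to 0.10 with the mean over cells of each cell's counts. The remaining ranked lists lay inside the range of random lists, and the median gene shifted by -0.04 log2.

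**Figure D2:**
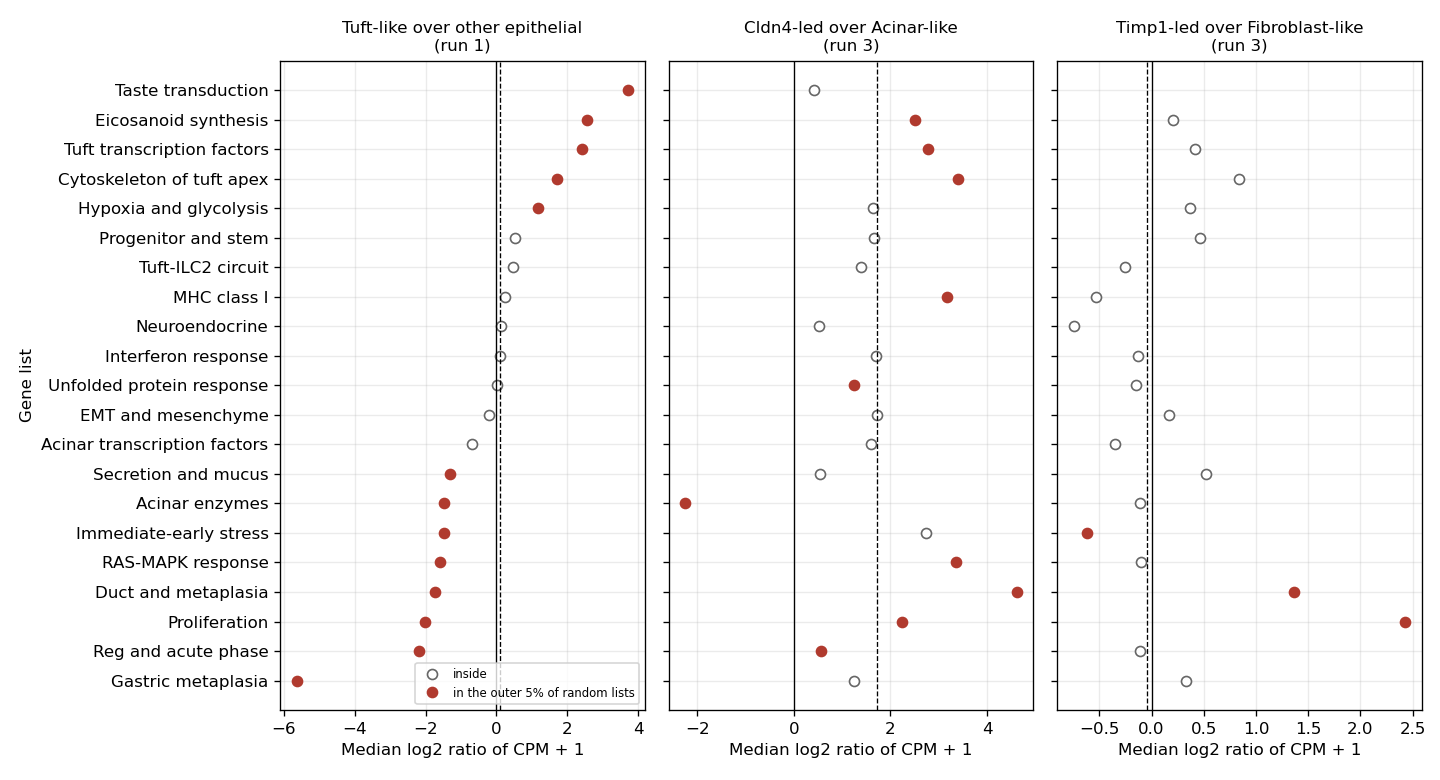
Median log2 ratio of CPM + 1 (x axis) of each gene list (y axis) in the 3 comparisons of cell sets; filled points lie in the outer 5% of 10000 matched random lists, and the dashed line is the median of all genes. Gastric metaplasia stands at -5.63 in Tuft-like cells and Proliferation at 2.43 in Timp1-led cells, while in the middle panel the Unfolded protein response and Reg and acute phase lie left of the median of all genes, and in the right panel Immediate-early stress changes sign with the mean over cells of each cell's counts.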

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

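Both results here are signals in barcodes that were left out of the comparisons; their tests were chosen after the result was seen. The rule that raised them compares a share with the limit that a count of 0 allows, which any sizeable share exceeds, so the shares in analysed cells stand beside them: Dclk1 was counted in 27.7% of all analysed cells and in 50.4% of those of run 1, unthinned, at a median of 5876 UMIs over the pool. Of 137 barcodes over the mitochondrial maximum that had enough genes, 51 held a Dclk1 UMI, 37.2% (exact 95% interval 29.1 to 45.9%; the limit at 0 is 2.19%), at a median of 1610 UMIs, and 82 of the 137 were in run 1. At least 3 Tuft markers other than Dclk1 were counted in 36.5% of them, and at least 3 of Pou2f3, Trpm5, Avil, Sh2d6, Rgs13, Gng13 and Nrgn in 31.4%. The first rule also called 35.1% of all analysed cells and 89.3% of Macrophage-like cells. The left-out barcodes had a median of 1610 UMIs against 5876 in the pool, so the 36.5 and 35.1% are not at equal depth. Their closeness therefore does not show that the left-out barcodes are like the pool. Without the mitochondrial maximum the Tuft-like class held 1072 of 6514 cells, against 991 of 6337 with it. For the second rule no share was taken in analysed cells. Of 115 called doublets, 88 held a Dclk1 UMI, 76.5% (67.7 to 83.9%; the limit at 0 is 2.61%), at a median of 11673 UMIs, and 99 of the 115 were in run 1. The same marker counts were reached by 82.6% and 66.1% of them.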

How the results depend on the processing

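The alternatives for the 3 comparisons of cell sets, the clustering without Dclk1, Spib, Kras and the list genes that are no markers, and the run without a mitochondrial maximum were chosen after seeing the data; the others were planned. The planned comparisons of the Tuft marker list between libraries, with all their alternatives, were not run, since no cell could be mapped to a library. No paired analysis was possible because no numbering pairs the libraries and each group has 1. The Tuft-like share stayed between 15.6 and 16.5% under other resolutions, numbers of variable genes and components, with doublets kept, in that clustering and without the mitochondrial maximum. It was 16.9% with at least 500 detected genes, where fewer cells form the total, 10.2% with at most 10% mitochondrial counts, which leaves out many cells of a class with a median of 9.53%, and 35.1% when cells were called one by one from 3 Tuft markers, a rule that also called 89.3% of Macrophage-like cells. The share of cells with Dclk1 was 27.7% without thinning and 21.7% thinned to 2000 UMIs, so it depends on depth.

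The Dclk1 log2 ratio of Tuft-like cells, 5.57, was 5.86 with the mean over cells of each cell's counts, 5.39 with median-of-ratios size factors, 5.38 with a pseudocount of 10 and 5.91 without the 5% of cells with the most UMIs. That of Cldn4-led cells, 6.18, was 7.01 with the mean over cells, 4.66 with size factors and 3.23 with a pseudocount of 10. In these 2 comparisons every alternative kept the direction. For Timp1-led cells it stayed between 0.52 and 0.81 around 0.72. Of the lists outside the random range in Cldn4-led cells, the sign changed for the Unfolded protein response (-1.24 with size factors, -0.16 without enzymes in the total) and for Reg and acute phase (-0.83 with size factors). These scalings shift every gene, the median gene from 1.73 to 0.03 and 0.88, and both lists lay below the median gene under each, so their place relative to it did not reverse. The sign also changed for lists inside the range or not ranked: Gastric metaplasia (-1.13 with size factors, -0.11 without enzymes), Secretion and mucus (-0.47, -0.12), and with size factors Acinar transcription factors, Hypoxia and glycolysis, Progenitor and stem, and Islet hormones. Immediate-early stress in Timp1-led cells was reversed (0.10 with the mean over cells, where the median gene was at -0.10), and the cause was not tested. All 13 lists outside the random range in Tuft-like cells stayed outside under all 10 alternatives, although the Proliferation median there was -0.72 without the Lypd8-led cells and that of Reg and acute phase -4.24 without the 1% of cells with the most enzyme UMIs. In Cldn4-led cells 7 of 10 did so with the mean over cells, 8 with size factors, 8 with a pseudocount of 10 and 9 without enzymes in the total.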

Other observations

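The tests on Dclk1 outside Tuft-like cells and on the spread of the enzyme UMIs and on 99% of the cells were chosen after the result was seen; those on the whole enzyme signal and on Ins2 were written down before their result. In the Cxcl13-led cluster, Cxcl13, a chemokine gene that attracts B cells, was counted in 31 of 69 cells, all in run 5. Of these 31 cells 27 also held Dclk1, and they carried all 114 Dclk1 UMIs of the cluster. Spib, which B cells also express, was counted in 34 of the 69 cells and in 22 of the 31 with Cxcl13; Cd79a or Cd79b was counted in 31 cells and a Cd3 gene in 24. Pou2f3 was not counted in this cluster.

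Dclk1 UMIs occurred outside the Tuft-like class, and RNA or doublets from tuft-like cells is a candidate explanation. Such RNA would bring Dclk1 and the other Tuft markers within 2-fold of their ratio in tuft-like cells, a bound set after the result was seen, but in run 3 the ratio of Dclk1 to those markers was 14.6 times (11.1 to 19.4) that in tuft-like cells for Fibroblast-like, 18.7 times (14.9 to 23.7) for Timp1-led and 11.5 times (9.39 to 14) for Cldn4-led cells, which argues against it there. In run 1 the ratio was 1.10 times (0.972 to 1.24) for Gastric-metaplasia-like and 0.714 times (0.574 to 0.88) for Gsta1-led cells, within that bound, although the interval for Gsta1-led cells lies below 1. Reads shared with an overlapping gene were not tested. The cells were sorted on the Dclk1 reporter, yet Dclk1 was counted in 38.4% of thinned cells in run 1. In runs 2 to 5 it was counted in 3.46, 3.70, 2.27 and 3.57% of thinned cells. Unthinned shares in runs 2 to 5 were 11.8, 13.8, 9.18 and 16.8%, so most sorted cells there had no Dclk1 UMI. Since no cell can be assigned to a group, no biological explanation was tested.

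Acinar enzyme UMIs in Tuft-like cells may come from free RNA of the run. Over all members the enzymes' shares of the list differed from those in other non-acinar cells of run 1 by a median of 0.294 log2 (range 0.028 to 2.34), under the bound of 0.5 set in advance. That value rests on a few cells on both sides, 9 of 978 Tuft-like cells with 79.8% of the UMIs and 15 of 1543 other cells with 84.1%. Free RNA was taken to reach cells about evenly, as Ins2 did in run 5, where free RNA is itself only a candidate. Over all 978 cells the variance of enzyme UMIs beyond counting error and depth was taken relative to the squared mean. It was 4829 times (2166 to 12223) that of Ins2 in run 5 (96.1 against 0.020). This value was taken once the concentration in 9 cells was known and restates it, so it is no separate support. Evenly spread free RNA alone would not give that concentration, although the bound on shares was met. For the other 99% of cells the median difference was 0.575 log2 (0.191 to 3.49), between the bounds of 0.5 and 1, so that free RNA and another source cannot be told apart at these counts; doublets with acinar cells stay open, and no biological explanation was tested.

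Ins2 was counted in 310 of the 310 cells of run 5 outside the Ins2-led cluster, at a median of 17 UMIs against 21412 in that cluster, and in 8.52, 0.406, 1.42 and 3.30% of such cells in runs 1 to 4. Free RNA from the Ins2-led cells is a candidate explanation: the ratio of Ins2 to 6 other genes of that cluster in the other cells was 0.773 times (0.615 to 0.986) that in the Ins2-led cells, within the 2-fold range that 1 source gives. The Cxcl13 and Dclk1 counts of run 5 were not part of this test. No biological explanation was tested.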
